A study of Homo sapiens with 18 samples.

How the data were processed

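Poly-A RNA of HEK293T cells was sequenced by the submitters with a dUTP strand-specific kit on a DNBSEQ-G400 instrument. The 18 libraries formed 6 groups of 3 from their labels: empty vector or methionaseNLS at 12 h in DMSO, and each of these at 24 h in DMSO or Vps34-IN1. All libraries carried a single batch label, so no batch difference could be examined.

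Per the submitters' processing notes, STAR 2.7.10b, featureCounts, DESeq2, limma and the hg38 build were used; the notes do not give the role of each tool. The annotation, the strand setting of the counting and any filter of genes were not given in the sources used here, so reads from overlapping genes on opposite strands may not have been told apart. The authors deposited 1 table of log2 values after a variance-stabilising transformation, with a lowest value of 5.45 log2. It held 37097 lines, of which 1 named no gene and took between 0.0% and 0.0022% of the reads of a library. Of the 37096 named genes, 36158 matched a symbol of the GRCh38.p14 gene table, which gave types and positions.

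The transformation was undone to recover read counts, and 100% of the values lay within 0.01 of a whole read, with a largest distance of 7.0e-09. Total reads ranged from 18278586 to 20825682, size factors from 0.89 to 1.1, and genes with at least 1 read from 24354 to 26380 per library. Normalised reads are counts divided by these size factors. Libraries of the same group were compared for duplicates by a chi-square per gene, which was 2.54 or more in every pair, so none was treated as a copy of another.

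Genes were tested when their mean over all libraries was at least 0.5 above the lowest value, which kept 17755. The deposited log2 values were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group and an empirical Bayes variance trend. The 8 comparisons were methionase against empty vector in 3 settings, the drug against DMSO in each vector, the methionase by drug and methionase by time interactions, and 24 h against 12 h with the empty vector. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 within a comparison, and a second count asked for a log2 difference of at least 1. No correction was made over the 8 comparisons.

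Before the data were examined, 36 gene lists of at least 5 tested genes were written and tested with camera at a preset correlation between genes of 0.01, adjusted over the 36 lists. Each was also tested with a correlation estimated from the data. Within a list, p-values were also adjusted over its members alone. Genes were named by a rule written beforehand. It took the 8 largest increases and 8 largest decreases among called genes with a symbol, leaving out clone-type names. Except for the interactions, the groups compared also had to show no overlap. The rule further took the called members of each list with the lowest adjusted p and called members that went against its majority. In addition, 10 genes were followed in every comparison. Other genes named as list examples, NEAT1 and the genes of the lists added later were chosen after their values were seen.

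The procedure was tested on simulated data with changes added to 50 genes per fold, drawn from genes with a mean of at least 50 normalised reads. The simulated spread followed a smooth trend with mean reads and was the same in every group. For a comparison of 2 groups, 12%, 86%, 98% and 100% of the genes changed by 1.2-fold, 1.5-fold, 2-fold and 4-fold were recovered, and 3.9% of the calls were false. For an interaction, the shares were 0%, 50%, 90% and 100%, and 3.2% of the calls were false. Far more genes were called in the data than were changed here, and genes with fewer reads were not drawn. These shares may therefore not hold for the data as a whole.

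Alternatives were no filter and a stricter filter at 1, which left 14322 genes, quantile normalization and equal library medians, a fit without the variance trend, array quality weights, a fit of only the groups compared, a replicate number block, an estimated list correlation and each replicate left out in turn. The limma voom method on the recovered counts was added after seeing the data. Values of a few single genes that the naming rule or the texts had picked are not reported here. Exons, splicing and sequence variants were left out because the table holds 1 value per gene.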

Results

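Poly-A RNA was measured in HEK293T cells, a human embryonic kidney line that is easy to transfect. Cells received the empty pLEX vector or methionaseNLS, a methionase carrying a nuclear localisation signal. Methionase breaks down methionine, the amino acid from which cells make S-adenosylmethionine, the methyl donor of histone and DNA methylation. No group was labelled as receiving an inactive methionase or another foreign protein. Methionase effects below are therefore differences from the empty vector. They cannot tell the activity of the enzyme from the expression of a foreign nuclear protein. RNA was taken after 12 h or 24 h of transfection. At 24 h, 2 further groups had been treated with 5 µM Vps34-IN1 for 12 h, an inhibitor of VPS34, the lipid kinase of the class 3 PI3K complex that is encoded by PIK3C3, and the other 4 groups had received the vehicle DMSO. The labels do not say whether DMSO was given for as long in every group, so differences between drug and DMSO and between 24 h and 12 h could include a difference in vehicle time. Each of the 6 groups held 3 libraries, 18 in all. Total reads assigned to genes ranged from 18278586 to 20825682 per library. The labels do not say that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Log2 differences are on the variance-stabilised scale, which understates the change of genes with few reads.

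The first principal component of the 18 libraries held 53.2% of the variance. It placed all libraries of the empty vector in DMSO and of methionase at 12 h between -27.44 and -14.93, and the other libraries between 6.72 and 29.42. The second component held 15.9% and placed the 3 libraries of the empty vector with Vps34-IN1 between -25.67 and -22.55, apart from the rest, which lay between -0.79 and 15.15.

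**Figure D1:**
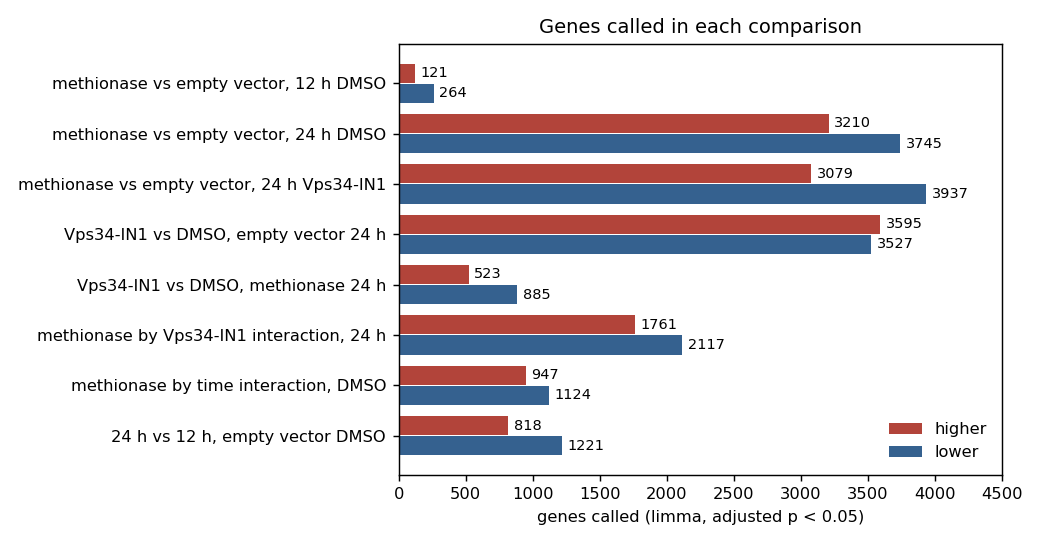
Number of genes called higher (red bars) and lower (blue bars) in each comparison, by limma at an adjusted p below 0.05 among 17755 genes tested. Methionase called 385 genes at 12 h and 6955 at 24 h, and Vps34-IN1 called 7122 genes in empty vector cells and 1408 in methionase cells.

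The comparison at 12 h asked what methionase had changed early. SLC2A1, the glucose transporter GLUT1, fell from 1299 ± 239.5 to 653 ± 34.45 normalised reads (SD, n = 3 per group), a log2 difference of -0.90 ± 0.09 (SE). EGLN1, a prolyl hydroxylase that marks HIF1A for destruction, had a log2 difference of -0.57 ± 0.07, the glycolysis regulator PFKFB4 one of -0.75 ± 0.10 and the transcription repressor BHLHE40 one of -0.80 ± 0.13. JUN, a subunit of the AP-1 transcription factor, rose by 0.86 ± 0.14, the small GTPase gene RHOB by 0.81 ± 0.13 and MYC, a growth-promoting transcription factor, by 0.40 ± 0.07. HSPA1B, an inducible HSP70 heat shock gene, rose by 1.03 ± 0.21, but it shares nearly all its sequence with HSPA1A, so its own value is uncertain. Without methionase 12 h replicate 2, RHOB (adjusted p = 0.05272), MYC (0.07677) and HSPA1B (0.07677) were no longer called, and HSPA1B was not called without empty vector 12 h replicate 2 (0.05569) or methionase 12 h replicate 3 (0.06275) either.

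Among the 37 tested genes of glycolysis and the hypoxia response, 11 fell and none rose over all genes tested, and 22 fell when adjusted over the list alone. Their median log2 difference was -0.27, or -0.16 without empty vector 12 h replicate 1 (camera, adjusted p = 4.57e-17 over 36 lists), and the call was lost at an adjusted p = 0.1966 with an estimated correlation. Of 44 genes of the G1/S transition and DNA replication, 5 fell, among them PCNA, the sliding clamp of DNA polymerase (-0.34 ± 0.06), and UNG, a uracil-DNA glycosylase (-0.35 ± 0.06), which were not called without methionase 12 h replicate 2 (adjusted p = 0.06752 and 0.06154). None of these 44 rose, 15 fell adjusted over the list alone, the median was -0.11 (-0.05 with quantile normalization) and the list was also called with an estimated correlation (adjusted p = 0.04897). Of 53 lysosome genes, 4 fell, all coding for subunits of the proton pump: ATP6V1C1 (-0.28 ± 0.06), ATP6V0E1 (-0.31 ± 0.07), ATP6V0D1 (-0.38 ± 0.09) and ATP6V1D (-0.25 ± 0.06). These calls were weak. With quantile normalization none of the 4 was called. With no filter ATP6V0D1 (adjusted p = 0.05894) and ATP6V1D (0.06684) were not called, nor was ATP6V1D without a variance trend (0.06179). ATP6V1D also lost its call without each of the 6 libraries in turn (adjusted p from 0.07125 without methionase replicate 3 to 0.1516 without methionase replicate 2). ATP6V0D1 lost it without each library but empty vector replicate 1 (0.07002 without methionase replicate 1 to 0.1318 without empty vector replicate 3), ATP6V1C1 without empty vector replicates 2 and 3 (0.07193 and 0.09604) and methionase replicates 1 and 2 (0.06707 and 0.09017), and ATP6V0E1 without empty vector replicate 3 (0.1211) and methionase replicates 1 and 2 (0.07098 and 0.1151). Adjusted over the list alone, 12 lysosome genes fell and 1 rose; the list call gave an adjusted p = 0.1020 with an estimated correlation. PIK3C3 itself fell by 0.23 ± 0.06 (limma, adjusted p = 0.04355), a call lost with quantile normalization (0.1010), with no filter (0.06698), without a variance trend (0.05649) and with a replicate number block (0.06048). PIK3C3 was also not called without each of the 6 libraries in turn (0.06009 without empty vector replicate 1 to 0.1773 without empty vector replicate 2). Its list of 42 class 3 PI3K and autophagy genes had 2 members lower and none higher (3 lower adjusted over the list alone). That list was called with a median of -0.08 (-0.04 with quantile normalization), a call lost with an estimated correlation (adjusted p = 0.1017) and with quantile normalization (adjusted p = 0.3219).

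Across 17755 genes, limma called 385 at 12 h, 121 higher and 264 lower. Only HSPA1B among them differed by at least 1 log2 on the variance-stabilised scale. On this scale, genes that changed 2-fold in reads can fall short of 1. Quantile normalization called 90 higher and 95 lower. The count rested on every library: it was 238, 98 and 62 without empty vector replicate 1, 2 and 3, and 92, 18 and 131 without methionase replicate 1, 2 and 3. It was 178 without the filter on low values, 247 without a variance trend, 2135 with array weights and 1561 when only these 6 libraries were fitted.

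The comparison at 24 h asked what methionase had changed later. H2BC21, a histone H2B gene, rose from 199.2 ± 18.35 to 6626 ± 2337 normalised reads (SD, n = 3 per group), a log2 difference of 4.52 ± 0.16 (limma, adjusted p = 2.16e-15). HSPA5, the ER chaperone BiP, rose from 10930 ± 654.3 to 65110 ± 15660 normalised reads, a log2 difference of 2.54 ± 0.13. CHAC1, a glutathione-degrading enzyme and a target of the stress transcription factor ATF4, fell from 822.4 ± 246.7 to 141.5 ± 29.06 normalised reads, a log2 difference of -2.02 ± 0.20. The linker histone gene H1-2 (2.83 ± 0.12), the matricellular protein gene CCN1 (2.702 ± 0.193), the stress transcription factor ATF3 (2.47 ± 0.22) and the AP-1 subunit FOS (2.38 ± 0.22) also rose.

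Of 18 replication-dependent histone genes, 16 rose and none fell, also when adjusted over the list alone. Their median log2 difference was 1.04, with H2BC5 (1.67 ± 0.09) and H1-4 (2.03 ± 0.12) as further examples, and the list was called with an estimated correlation as well (adjusted p = 0.03396). Histone genes are close copies of one another, so reads could be shared between members and single values are uncertain. Most transcripts of this class carry no poly-A tail, and the share of all reads that fell on 62 such genes was 0.0189% ± 0.0008 with the empty vector and 0.0888% ± 0.0188 with methionase (SD, n = 3 per group). The share on the 2 mitochondrial rRNA genes moved in the same groups, from 0.548% ± 0.0956 to 1.49% ± 0.536.

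Of 29 immediate early genes, 17 rose and 1 fell (18 and 2 adjusted over the list alone), with a median of 0.46. JUN rose by 2.17 ± 0.14, the phosphatase gene DUSP1 by 2.30 ± 0.18 and IER2 by 1.03 ± 0.06, whereas the zinc finger transcription factor EGR1 fell by 1.07 ± 0.12. This list was not called with an estimated correlation (adjusted p = 0.3054). Of 77 cytosolic ribosomal protein genes, 48 rose and none fell (54 adjusted over the list alone), with a median of 0.29 that was 0.11 with quantile normalization, for example RPL24 (0.45 ± 0.07) and RPL26 (0.48 ± 0.08). That call had an adjusted p = 0.4977 with an estimated correlation. In the heat shock list, 14 of 22 genes rose and 1 fell (16 and 1 adjusted over the list alone), with CHORDC1, an HSP90 co-chaperone, at 0.61 ± 0.08 and DNAJA1, an HSP40 co-chaperone, at -0.58 ± 0.07 (adjusted p = 0.4366 with an estimated correlation).

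Of 39 genes of the ATF4 and amino acid response, 27 fell and 5 rose (28 and 5 adjusted over the list alone), with a median of -0.51. The glycine transporter SLC6A9 (-1.01 ± 0.08), the neutral amino acid transporter SLC1A4 (-1.10 ± 0.10) and SESN2, a leucine sensor upstream of mTORC1 (-1.07 ± 0.14), were lower, as was the pseudokinase gene TRIB3 (-0.76 ± 0.15). Asparagine synthetase, ASNS (0.55 ± 0.14), and DDIT3, which codes for the stress factor CHOP (0.65 ± 0.20), rose, and ATF4 itself was not called (-0.16 ± 0.09, adjusted p = 0.1348), although it was with quantile normalization (-0.37 ± 0.07). The DDIT3 call was lost without empty vector 24 h replicate 3 (0.48 ± 0.21, adjusted p = 0.08116). This list had an adjusted p = 0.4977 with an estimated correlation. Of 44 G1/S and replication genes, 32 fell and 2 rose (33 and 2 adjusted over the list alone), with a median of -0.33, such as the DNA repair gene BRCA1 (-0.69 ± 0.06), thymidylate synthase TYMS (-0.54 ± 0.07) and UHRF1, which recruits the maintenance DNA methyltransferase (-0.51 ± 0.06). The G1/S call held with an estimated correlation (adjusted p = 0.0311). In the glycolysis and hypoxia list, 25 of 37 fell and none rose (25 adjusted over the list alone), with SLC2A1 at -1.14 ± 0.09 and a median of -0.33 (adjusted p = 0.4977 with an estimated correlation).

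Single chromatin and methionine genes were called in both directions at 24 h. TET1, which oxidises 5-methylcytosine, rose by 0.84 ± 0.09, and the lysine methyltransferase gene SETD7 fell by 0.87 ± 0.07. SAT1, an enzyme of polyamine breakdown, rose by 1.96 ± 0.14 and AMD1, which uses S-adenosylmethionine to make polyamines, fell by 0.53 ± 0.07. MAT2A, which makes S-adenosylmethionine, was not called (-0.36 ± 0.17, adjusted p = 0.1029) except without methionase 24 h replicate 3 (-0.52 ± 0.18, adjusted p = 0.02927). PIK3C3 fell from 683.9 ± 23.06 to 412.4 ± 11.56 normalised reads (log2 difference -0.63 ± 0.06), PIK3R4, the regulatory subunit of the same complex, fell by 0.36 ± 0.06, and PPARA, a nuclear receptor of the fasting response, fell by 0.54 ± 0.08. The lists of DNA methylation enzymes, histone methyltransferases, methionine cycle genes and class 3 PI3K genes were not called by camera in this comparison.

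Limma called 6955 genes at 24 h, 3210 higher and 3745 lower, of which 131 rose and 38 fell by at least 1 log2. With equal library medians the majority turned, with 4012 higher and 3176 lower. Of the genes called at 12 h, 94 were also higher and 239 also lower at 24 h, where independent lists would give 21.9 and 55.7. The log2 differences at the 2 times had a Pearson correlation of 0.556 and a Spearman correlation of 0.542 across 17755 genes, which are not independent replicates.

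**Figure D2:**
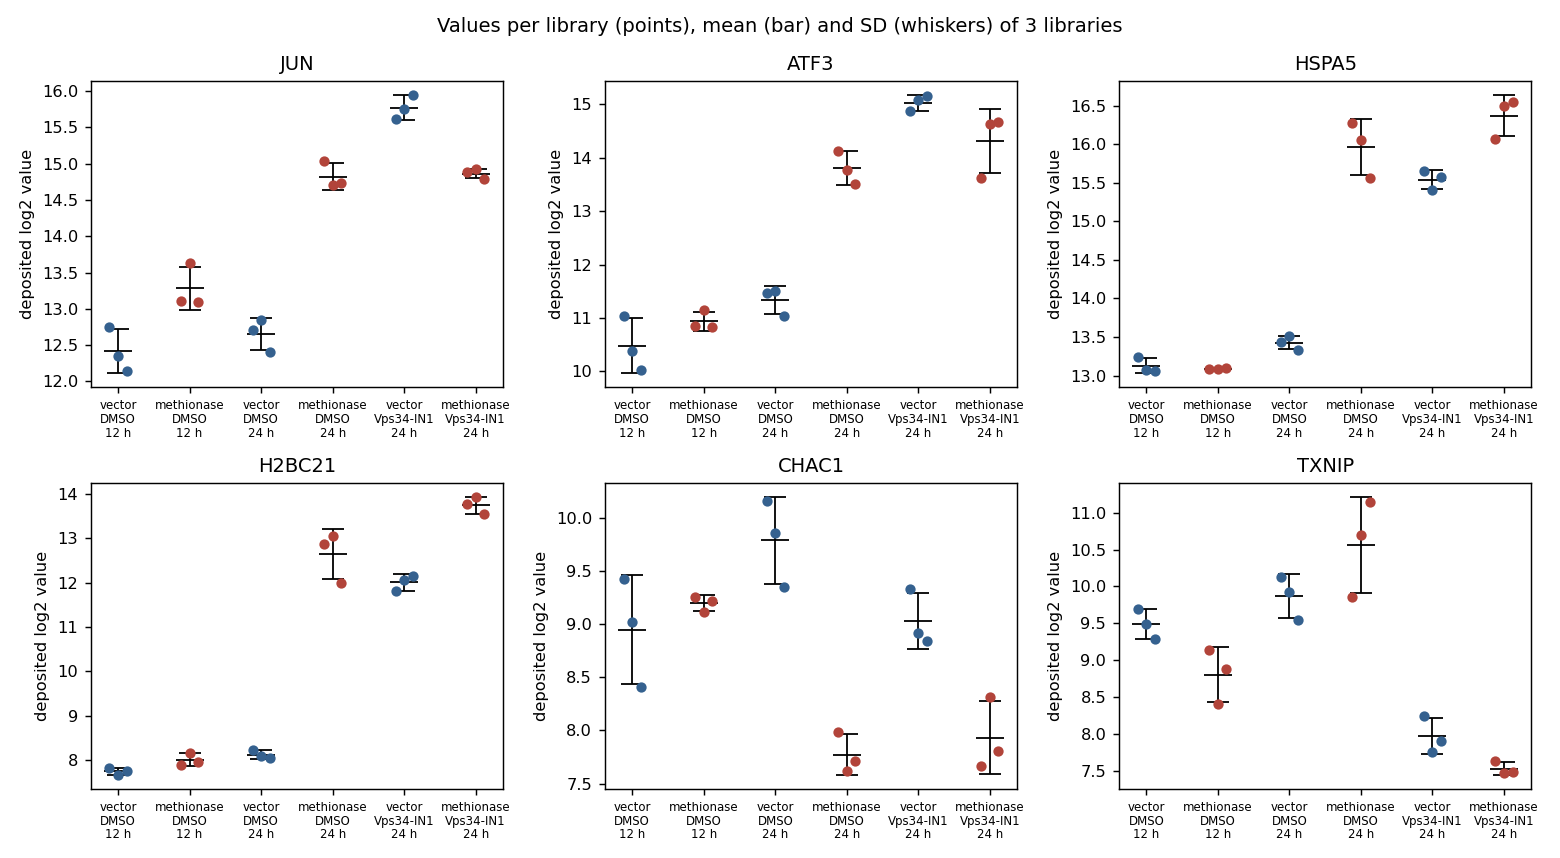
Deposited log2 values of JUN, ATF3, HSPA5, H2BC21, CHAC1 and TXNIP in each library (points, blue for the empty vector and red for methionase), with the mean of 3 libraries (bar) and its SD (whiskers); each panel has its own vertical axis, which does not start at 0. JUN was higher with Vps34-IN1 in empty vector cells than in any other group, and TXNIP was lower in both Vps34-IN1 groups than in the DMSO groups.

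Vps34-IN1 in empty vector cells asked what the drug did without methionase. RHOB rose from 4395 ± 543.3 to 66350 ± 4916 normalised reads (SD, n = 3 per group), a log2 difference of 3.90 ± 0.13 (limma, adjusted p = 2.83e-16), and JUN from 6418 ± 972.6 to 56160 ± 6593, a log2 difference of 3.12 ± 0.14. H2BC21 (3.88 ± 0.16), ATF3 (3.69 ± 0.22), CCN1 (3.37 ± 0.19), H1-2 (3.01 ± 0.12) and the orphan nuclear receptor NR4A1 (2.90 ± 0.16) rose as well. TXNIP, an arrestin-like protein that limits glucose uptake, fell from 862.3 ± 188.3 to 173.6 ± 43.66 normalised reads, a log2 difference of -1.90 ± 0.21. MAT2A fell by 1.27 ± 0.17, and the RNA-binding protein gene RBM12 (-1.94 ± 0.07), the chemokine receptor CXCR4 (-1.53 ± 0.12) and the apoptosis regulator BMF (-1.29 ± 0.09) were lower.

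Of 29 immediate early genes, 21 rose and 3 fell with the drug (21 and 4 adjusted over the list alone), with a median of 0.95. KLF6, a zinc finger transcription factor, rose by 2.49 ± 0.12, DUSP1 by 2.84 ± 0.18 and MYC by 1.51 ± 0.07, while EGR1 fell by 1.01 ± 0.12 (list adjusted p = 0.1781 with an estimated correlation). Of 28 genes of the ER unfolded protein response, 20 rose and 1 fell, also adjusted over the list alone, with a median of 0.42 (adjusted p = 0.2008 with an estimated correlation). Examples were HSPA5 (2.12 ± 0.13), HERPUD1 of ER-associated degradation (1.78 ± 0.13), and the ER stress sensors EIF2AK3 (0.83 ± 0.09) and ERN1 (0.86 ± 0.10). Of 18 histone genes, 15 rose and none fell (17 adjusted over the list alone), with a median of 1.17 (adjusted p = 0.07829 with an estimated correlation). Reads on histone genes made up 0.0848% ± 0.0089 with the drug against 0.0189% ± 0.0008 without it, and mitochondrial rRNA made up 1.2% ± 0.193 against 0.548% ± 0.0956 (SD, n = 3 per group).

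In the cholesterol list, 12 of 27 genes rose and 5 fell, also adjusted over the list alone: IDI1, an isomerase of isoprenoid synthesis, rose by 2.01 ± 0.09 and HMGCS1 by 0.99 ± 0.10, whereas lanosterol synthase LSS fell by 0.42 ± 0.08. This call was lost with an estimated correlation (adjusted p = 0.6080) and with quantile normalization (adjusted p = 0.09392). In the glycolysis and hypoxia list, 18 of 37 genes fell and 1 rose (18 and 2 adjusted over the list alone), with the pyruvate dehydrogenase kinase PDK3 at -0.88 ± 0.08 and the glucose transporter SLC2A3 at -1.40 ± 0.15 (adjusted p = 0.6080 with an estimated correlation). Ribosomal protein genes had 31 members of 77 higher and none lower (34 higher adjusted over the list alone) and a median of 0.20, which turned to -0.02 and lost its call with quantile normalization; the adjusted p was 0.6080 with an estimated correlation. The class 3 PI3K and autophagy list was not called, although GABARAPL1, an ATG8 family gene, rose by 1.31 ± 0.12 and PIK3C3 fell by 0.42 ± 0.06.

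Limma called 7122 genes with the drug in empty vector cells, 3595 higher and 3527 lower; with equal library medians the split was 4544 higher and 2831 lower, and with quantile normalization it was 3299 higher and 3500 lower. The 97 that rose and 49 that fell by at least 1 log2 included RHOB and RBM12. Methionase at 24 h and the drug were measured against the same 3 control libraries. Their log2 differences correlated with a Pearson r of 0.64 across genes. Unchanged groups and shared controls, all simulated with equal spread, gave 0.5. That value is set in advance by the sharing, so it does not measure how much of the 0.64 came from the controls. The covariance was 0.0603 against a simulated 0.00399, a difference of 0.0563. They shared 1658 higher and 1957 lower genes, where independent lists would share 650 and 743.9, and part of this excess may come from the shared controls, since 3 libraries cannot be split into parts of 2 or more.

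**Figure D3:**
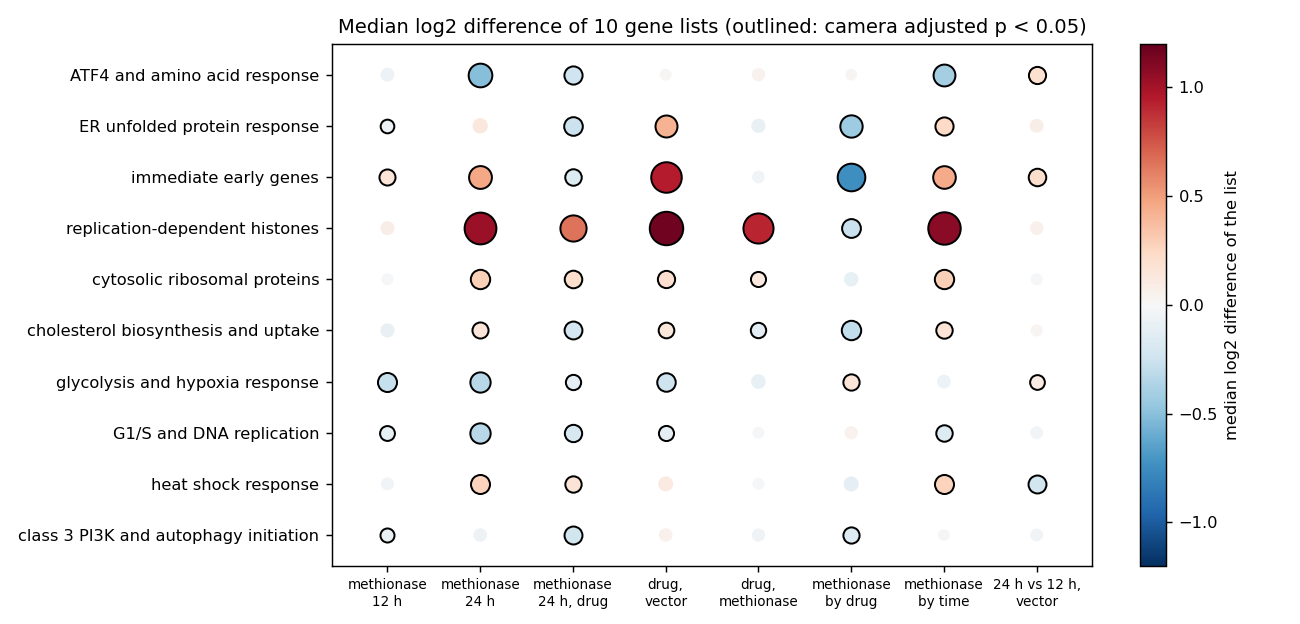
Median log2 difference of 10 gene lists (vertical axis) in the 8 comparisons (horizontal axis), shown by colour and by the size of the point; a black outline marks lists called by camera at an adjusted p below 0.05 with the preset correlation. The median of the immediate early genes was 0.95 with the drug in empty vector cells and -0.17 with methionase in drug-treated cells, where it was -0.29 and -0.35 without methionase Vps34-IN1 replicates 2 and 3; the median of ribosomal protein genes with the drug in empty vector cells turned to -0.02 with quantile normalization.

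Vps34-IN1 in methionase cells asked what the drug did when methionase was present. TXNIP fell from 1531 ± 666.7 to 108 ± 11.06 normalised reads (SD, n = 3 per group), a log2 difference of -3.04 ± 0.21 (limma, adjusted p = 3.65e-09). ARRDC4, an arrestin related to TXNIP, fell by 1.40 ± 0.11 and CUL3, a ubiquitin ligase scaffold, by 1.01 ± 0.07. All 3 NR4A nuclear receptor genes rose: NR4A2 by 1.84 ± 0.16, NR4A1 by 1.37 ± 0.16 and NR4A3 by 1.12 ± 0.15. MYC rose by 0.73 ± 0.07, and PIK3C3 (0.04 ± 0.06, adjusted p = 0.7777) and MAT2A (-0.18 ± 0.17, adjusted p = 0.5773) were not called.

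Of 18 histone genes, 15 rose and none fell (16 adjusted over the list alone), such as H4C5 (1.75 ± 0.16) and H2BC12 (0.92 ± 0.07), with a median of 0.92, and this list was called with an estimated correlation (adjusted p = 0.005248). The share of reads on histone genes was 0.1893% ± 0.017 with both treatments, and that on mitochondrial rRNA was 2.18% ± 0.288 (SD, n = 3). Of 27 cholesterol genes, 7 fell and 1 rose (8 and 1 adjusted over the list alone), among them squalene epoxidase SQLE (-0.48 ± 0.07) and MSMO1, a sterol oxidase (-0.36 ± 0.06), with an adjusted p = 0.4452 for the list with an estimated correlation. The immediate early list and the ER list were not called in this comparison. Limma called 1408 genes, 523 higher and 885 lower; with equal library medians 899 were higher and 605 lower. The count was 860 without methionase DMSO replicate 3, 625 with array weights and 296 when only these 6 libraries were fitted.

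Methionase in drug-treated cells asked how methionase and empty vector cells differed when both had received Vps34-IN1. The drug was present for 12 h of the 24 h of transfection, so the difference could include methionase effects from before it was added. Histone genes rose again, with 14 of 18 higher and none lower, also adjusted over the list alone, and a median of 0.66 (adjusted p = 0.1033 with an estimated correlation). The share of reads on mitochondrial rRNA moved in the same groups, from 1.2% ± 0.193 to 2.18% ± 0.288 (SD, n = 3 per group). That on small nucleolar RNAs went from 0.0251% ± 0.0057 to 0.0797% ± 0.0079. H4C5 rose by 2.10 ± 0.16 and H2BC21 by 1.74 ± 0.16. The pseudokinase gene TRIB1 (-1.95 ± 0.10), RHOB (-1.55 ± 0.13), the ER stress sensor EIF2AK3 (-1.36 ± 0.09) and KLF6 (-1.28 ± 0.12) fell. MAT2A rose by 0.73 ± 0.17, and CHAC1 (-1.10 ± 0.20) and SESN2 (-1.12 ± 0.14) were lower, as they were with methionase in DMSO.

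In this comparison 23 of 36 lists were called, 19 of them lower, and only 1 was called with an estimated correlation, so a lower list was common here. Of 42 class 3 PI3K and autophagy genes, 27 fell and 2 rose (29 and 2 adjusted over the list alone), with a median of -0.23 (-0.13 with quantile normalization), and this list was called with an estimated correlation (adjusted p = 0.02621). PIK3R4 fell by 0.71 ± 0.06, RB1CC1, a subunit of the ULK1 kinase complex, by 0.51 ± 0.07 and the autophagy receptor gene SQSTM1 by 0.41 ± 0.06, and PIK3C3 had a log2 difference of -0.17 ± 0.06. The PIK3C3 call was lost with quantile normalization (adjusted p = 0.2309), with equal library medians (0.06941), when only these 6 libraries were fitted (0.1296), and without empty vector Vps34-IN1 replicate 3 (0.1376) or methionase Vps34-IN1 replicate 3 (0.07319). Of 28 ER genes, 19 fell and 1 rose, also adjusted over the list alone, with SEL1L of ER-associated degradation at -0.79 ± 0.07 and HSPA5 as the member that rose (0.83 ± 0.13); the list had an adjusted p = 0.2136 with an estimated correlation. Of 29 immediate early genes, 13 fell and 5 rose, also adjusted over the list alone, with the transcription factor SRF at -0.93 ± 0.06 and NR4A2 at 1.21 ± 0.16. This call was lost with an estimated correlation (adjusted p = 0.3849) and without methionase Vps34-IN1 replicate 1 (adjusted p = 0.08385). Of 39 ATF4 and amino acid genes, 21 fell and none rose (23 adjusted over the list alone), with the transporters SLC38A2 at -0.86 ± 0.09 and SLC7A5 at -0.76 ± 0.10 (adjusted p = 0.3431 with an estimated correlation).

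Limma called 7016 genes for methionase in drug-treated cells, 3079 higher and 3937 lower, 88 and 25 of them by at least 1 log2. With equal library medians the majority turned, with 3738 higher and 3429 lower. Of the genes called with the drug, 1245 were also higher and 1846 also lower with methionase in DMSO, where independent lists would share 556.7 and 830.4, and 302 and 206 went in opposite directions. The Pearson correlation of the log2 differences was 0.499 and the Spearman correlation 0.451. The drug effects in empty vector and methionase cells had a Pearson correlation of 0.343 and a Spearman correlation of 0.263, and shared 267 higher and 433 lower genes, where independent lists would share 105.9 and 175.8. These are 4 relations between comparisons computed across 17755 genes, without p-values.

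The interaction tested whether the methionase effect at 24 h differed between Vps34-IN1 and DMSO, and a negative value means a lower methionase effect with the drug. RHOB had an interaction of -3.90 ± 0.19 (limma, adjusted p = 1.55e-12): it rose with methionase or the drug alone and stood at 22880 ± 4445 normalised reads with both (SD, n = 3), against 66350 ± 4916 with the drug alone. CCN1 (-3.87 ± 0.27), ATF3 (-3.19 ± 0.32), JUN (-3.08 ± 0.20) and KLF6 (-2.53 ± 0.17) were also less than additive on the log2 scale. SLC2A3 (1.41 ± 0.21), MAT2A (1.09 ± 0.24), UHRF1 (0.72 ± 0.09) and PIK3C3 (0.46 ± 0.09) had positive interactions.

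Of 29 immediate early genes, 19 had a negative and 1 a positive interaction (20 and 1 adjusted over the list alone), with a median of -0.75 (adjusted p = 0.1363 with an estimated correlation). Of 28 ER genes, 19 were negative and none positive (20 adjusted over the list alone), with HSPA5 at -1.71 ± 0.18, SEC24D of the vesicle coat COPII at -1.17 ± 0.10 and a median of -0.43 (adjusted p = 0.1363 with an estimated correlation). Of 27 cholesterol genes, 14 were negative and none positive (16 and 2 adjusted over the list alone), with IDI1 at -1.68 ± 0.13 and INSIG1, which retains the sterol sensor in the ER, at -1.32 ± 0.13 (adjusted p = 0.1926 with an estimated correlation). Of 18 histone genes, 7 were negative, also adjusted over the list alone, among them H2BC21 (-2.78 ± 0.23) and H1-4 (-1.79 ± 0.17), with an adjusted p = 0.5023 with an estimated correlation. The class 3 PI3K and autophagy list had 14 negative and 4 positive members of 42 (15 and 4 adjusted over the list alone) and a median of -0.16; its call ended with an estimated correlation (adjusted p = 0.1926), with quantile normalization (0.1108), without empty vector Vps34-IN1 replicate 1 (0.06232) and without methionase Vps34-IN1 replicate 3 (0.06796). Limma called 3878 interactions, 1761 positive and 2117 negative, 20 and 74 of them of at least 1 log2. With quantile normalization 1848 were positive and 1800 negative.

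The methionase effect also differed between 24 h and 12 h in DMSO. H2BC21 (4.25 ± 0.23), FOS (2.71 ± 0.31), H1-2 (2.63 ± 0.18) and HSPA5 (2.58 ± 0.18) had the largest positive differences among the genes named by size, and CHAC1 (-2.26 ± 0.28) the largest negative one. Of 18 histone genes, 14 were positive and none negative, also adjusted over the list alone, with a median of 1.09, and the list was called with an estimated correlation (adjusted p = 0.01777). Of 39 ATF4 and amino acid genes, 17 were negative and 2 positive (22 and 3 adjusted over the list alone), with SLC6A9 at -0.88 ± 0.11 and PPP1R15A, a phosphatase subunit that reverses eIF2α phosphorylation, at 1.35 ± 0.19 (adjusted p = 0.4986 with an estimated correlation). Limma called 2071 genes, 947 positive and 1124 negative; with equal library medians 1431 were positive and 722 negative. The count was 1276 without methionase 12 h replicate 1, 1325 without empty vector 24 h replicate 1, and 3617 with array weights.

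Empty vector cells at 24 h and 12 h were compared to see what time after transfection did without methionase. HSPH1, an HSP110 chaperone (-0.55 ± 0.06), HSP90AA1, an inducible HSP90 (-0.56 ± 0.10), and STIP1, which links HSP70 and HSP90 (-0.43 ± 0.06), fell, as did the kinesin gene KIF20A (-0.36 ± 0.06) and DLGAP5, a spindle protein gene (-0.47 ± 0.07). EGR1 rose by 0.98 ± 0.12 and VEGFA, an angiogenic growth factor, by 0.48 ± 0.08. Of 22 heat shock genes, 13 fell and 1 rose (15 and 1 adjusted over the list alone), and of 40 mitosis genes, 19 fell and none rose (25 adjusted over the list alone); both lists had an adjusted p = 0.1918 with an estimated correlation. The genes with the largest decreases by the naming rule were mostly copies of other genes, such as the ribosomal protein pseudogene RPL39P3 (446.5 ± 19.28 to 78.95 ± 16.97 normalised reads, log2 difference -1.79 ± 0.11) and EIF3CL (-1.24 ± 0.12), and these values are uncertain because reads could be shared with near-identical genes.

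Limma called 2039 genes between the times, 818 higher and 1221 lower; with equal library medians 640 were higher and 1668 lower, and with quantile normalization 830 were higher and 840 lower. The count was 1028 and 833 without empty vector 12 h replicates 2 and 3, 798 and 1256 without 24 h replicates 1 and 3, 1290 without the filter on low values, 5186 with array weights and 3507 when only these 6 libraries were fitted.

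In the GRCh38.p14 assembly the genes with these values lay as follows. JUN is on chromosome 1 from 58780791 to 58784047, H2BC21 on chromosome 1 from 149884459 to 149886682 and TXNIP on chromosome 1 from 145992435 to 145996579. RHOB is on chromosome 2 from 20447074 to 20449440, HSPA5 on chromosome 9 from 125234853 to 125241343, CHAC1 on chromosome 15 from 40953471 to 40956512 and PIK3C3 on chromosome 18 from 41955234 to 42087830. All are protein-coding genes. Each gene has a single value per library, so exons and untranslated regions were not told apart. Whether reads in introns were counted is not known.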

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

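The test of a ceiling on expression and the grouping of splits by what they kept whole were chosen after the result was seen; the tests of scaling, of single libraries and of other splits were planned, although the bound for the median was set with the median of the list known.

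The results in this part were taken up because a test of the difference itself showed that the methionase effect was not the same in 2 settings. For the drug, 3878 genes had an interaction. The medians of the lists were -0.75 for immediate early genes, -0.43 for the ER unfolded protein response, -0.29 for cholesterol genes, -0.26 for histones, -0.16 for class 3 PI3K and autophagy genes and 0.16 for glycolysis and hypoxia genes. All 6 lists lost their call with an estimated correlation. The last had 10 members positive and 1 negative of 37, and its call ended without empty vector DMSO 24 h replicate 2 (adjusted p = 0.06551), methionase DMSO 24 h replicate 3 (0.09335), empty vector Vps34-IN1 replicate 2 (0.06613) or replicate 3 (0.05801), or methionase Vps34-IN1 replicate 2 (0.1925, median 0.10).

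The genes with the largest negative interactions under the naming rule were RHOB (-3.90), CCN1 (-3.87), ATF3 (-3.19), JUN (-3.08), H2BC21 (-2.78), KLF6 (-2.53), the protease gene ADAMTS1 (-2.50) and DUSP1 (-2.46). Genes with large positive interactions were SLC2A3 (1.41), RBM12 (1.335), the mitochondrial cytochrome b gene CYTB (1.32), the coactivator gene NCOA5 (1.21), EMILIN3 (1.2), ZNF587B (1.16) and FASTKD5 of mitochondrial RNA processing (1.12).

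The less than additive response of immediate early genes was weighed against technical explanations. After quantile normalization the median interaction was -0.707, and with 1 of 12 libraries left out the median closest to 0 was -0.678, without methionase Vps34-IN1 replicate 1, so neither the scaling nor a single library accounted for it. A ceiling on expression would leave the genes as high with both treatments as with the drug alone, yet 12 of the 21 members that rose with the drug alone were lower with both. The same empty vector Vps34-IN1 libraries served to pick these members and to compare them, so values high by chance there would raise this count. A biological explanation, that methionase limits the response of these genes to the drug, may hold as a hypothesis, and a different state of the cells when the drug was added stays open and was not tested.

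Of 100 splits of the 12 libraries, 2, the real one included, gave as many interactions with the drug as the real 3878, a share under 0.05, and the highest other split called 4501. These splits exchange libraries between groups that differ by the methionase effect itself. The 80 that mixed the groups in both settings called no gene, the 12 that kept them whole with the drug alone called between 587 and 4501, and the 7 that kept them whole in DMSO alone called between 948 and 3440. They therefore compare the real grouping with a mixture and do not test for the absence of an interaction, and the count of 2 alone does not exclude chance for it.

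For time, 2071 genes differed in their methionase effect between 24 h and 12 h. The list medians were 1.09 for histones, 0.45 for immediate early genes, 0.29 for ribosomal protein genes, 0.27 for heat shock genes, 0.24 for the ER unfolded protein response, 0.21 for the respiratory chain, 0.16 for cholesterol genes, -0.17 for G1/S genes and -0.41 for ATF4 and amino acid genes. With quantile normalization the median was 0.07 for ribosomal protein genes, 0.17 for heat shock genes and 0.16 for the ER unfolded protein response, and with equal library medians that of G1/S genes was -0.11. Of these 9, histones alone were called with an estimated correlation. The largest positive genes under the naming rule were H2BC21 (4.25), FOS (2.71), H1-2 (2.63), HSPA5 (2.58), CCN1 (2.55), the histone gene H2BU1 (2.25), ATF3 (2.01) and H1-4 (1.94). The largest negative ones were CHAC1 (-2.26), SLC16A13 of the monocarboxylate transporters (-1.13), the translation factor gene EIF5 (-1.07), the peptide hormone gene ADM2 (-1.06), the pseudogene CENPBD1P (-1.05), LCMT2 of tRNA modification (-1.03), the mitochondrial pseudogene MTND2P28 (-1.02) and SESN2 (-1.001). H2BU1 was not called with voom (adjusted p = 0.05165), where its value was larger and less certain (3.774, SE 1.255). MTND2P28 lost its call with no filter (adjusted p = 0.1160), quantile normalization (0.05275), equal library medians (0.05278), no variance trend (0.06735) and only the groups compared (0.05636), and without empty vector 12 h replicate 1 (adjusted p = 0.1454), methionase 12 h replicates 1 and 3 (0.1101 and 0.1141), empty vector 24 h replicates 1 and 3 (0.07391 and 0.09996) and methionase 24 h replicates 1 and 2 (0.1308 and 0.06535). The values of the pseudogenes and histones are uncertain because their sequence is shared.

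For this interaction, 12 of 100 splits gave as many genes as the real 2071 and the highest other split gave 6631. Such high counts follow from how the splits are made, since they keep the methionase effect at 24 h while mixing or turning the one at 12 h. Every other split with as many genes kept the groups whole at 24 h: 10 mixed them at 12 h and called between 2341 and 4802, and 1 kept them whole at 12 h with exchanged labels and called 6631. The 78 splits that mixed both times and the 10 that mixed 24 h alone called no gene. As for the drug, these splits do not test for the absence of an interaction, so no conclusion about chance is drawn from them.

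The simple comparisons of 3 with 3 libraries have 10 splits, too few for a share under 0.05. The real split was the 1 split that called as many genes in each of them. Every other split mixes the groups compared, which moves their difference into the spread. Low counts in those splits were thus largely set in advance and are no evidence for the calls. The real counts and the highest other were 385 and 0 for methionase at 12 h, 6955 and 1 at 24 h, 7016 and 0 with the drug, 7122 and 0 for the drug with the empty vector, 1408 and 20 with methionase, and 2039 and 0 for time.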

How the results depend on the processing

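The fit with voom was chosen after seeing the data. In the order methionase at 12 h, at 24 h and with the drug, the drug with empty vector and with methionase, the drug interaction, the time interaction and time, the counts with voom were 478, 6962, 6851, 7222, 1279, 3818, 2110 and 2282, all within 1.5 times of the reported ones. Methionase at 12 h called 178 genes with no filter, 185 with quantile normalization, 247 without a variance trend, 2135 with array weights and 1561 with only the groups compared. Time called 1290 with no filter, 5186 with array weights and 3507 with only the groups compared. The drug in methionase cells called 625 with array weights and 296 with only the groups compared. The time interaction called 3617 with array weights. The main fit used 1 estimate of the spread for all groups, unlike the fits with array weights or only the groups compared. The chi-square per gene within a group was 8.929 to 24.668 for methionase in DMSO at 24 h. It was 9.257 to 13.972 for methionase with the drug and 2.535 to 12.815 in the other groups. Whether unequal spread or another cause moved these counts was not tested. With 1 replicate left out, counts ran from 18 to 238 for methionase at 12 h, 1276 to 2413 for the time interaction, 798 to 1696 for time and 860 to 1526 for the drug in methionase cells, with fewer samples in each fit. The number of lists called for the drug interaction ran from 5 to 11. Over the named genes and all alternatives, no value reversed, 2708 stayed on their side of the threshold, 61 lost their call and 2 gained one.

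With an estimated correlation, the lists called fell from 11, 11, 23, 8, 11, 6, 9 and 14 of 36 to 1, 2, 1, 0, 1, 0, 1 and 0 in the same order, since genes of a list that vary together count for less. Replicate numbers did not pair the libraries: over 15 pairs of groups the mean correlation of same-numbered libraries ran from -0.242 to 0.209, 13 of 45 same-numbered pairs exceeded 0.1, and 6 of 18 libraries correlated best with their own number. A block for replicate number gave 341, 6858, 6951, 7076, 1387, 3769, 2009 and 1971 genes and ended the call of PIK3C3 for methionase at 12 h (adjusted p = 0.06048). At a depth of 18278586 to 20825682 reads, changes of 1.2-fold were recovered for 12% of simulated genes in a comparison and 0% in an interaction. Genes with few reads were not among those changed, so uncalled genes may still differ by that much or more. In the data, the count for methionase at 12 h was 178 with no filter.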

Other observations

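The lists in this part and the tests of RNAs without a poly-A tail, of snoRNAs with 1 library left out and of ribosomal protein pseudogenes were chosen after the result was seen.

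Small nucleolar RNAs, which guide chemical modification of ribosomal RNA, were higher with methionase at 24 h, with 139 of 166 higher and 1 lower and a median log2 difference of 0.65 (camera, adjusted p = 0.04461 with an estimated correlation). At 12 h none of the 166 was called as a single gene, while the list was called with a median of 0.08 at the preset correlation (adjusted p = 7.99e-05) and not with an estimated one (0.6672). With the drug alone 58 were higher and none lower (median 0.20, adjusted p = 0.5419 with an estimated correlation). Their share of all reads was 0.0149% ± 0.0033 with the empty vector and 0.0538% ± 0.0176 with methionase at 24 h (SD, n = 3 per group). The share of mitochondrial rRNA was higher in the same libraries, at 1.49% ± 0.536 against 0.548% ± 0.0956, and among the methionase libraries in DMSO at 24 h both shares were highest in replicate 2 (0.0739% and 2.008%). With methionase in drug-treated cells 137 were higher and none lower (median 0.71, adjusted p = 0.06219 with an estimated correlation), among them SNORD74 (1.98 ± 0.12). A list of 26 genes that host snoRNAs was picked by name, mostly SNHG genes, so ribosomal protein genes among the hosts were left out. Of these 26, 21 were higher with methionase at 24 h (median 0.49, adjusted p = 0.003942 with an estimated correlation) and 16 with the drug alone (median 0.34, adjusted p = 0.01542 with an estimated correlation). Over the hosts matched to 160 snoRNAs, ribosomal protein genes included, the median with methionase at 24 h was 0.263. Zinc finger genes of the ZNF family had 170 members lower and 46 higher of 396 with methionase at 24 h (median -0.17, adjusted p = 0.1264 with an estimated correlation).

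Methionase in drug-treated cells also raised NEAT1, the RNA scaffold of paraspeckles (1.86 ± 0.27), and lowered CDKN1A, the cell cycle inhibitor p21 (-1.02 ± 0.08).

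Technical explanations of the higher snoRNAs with methionase at 24 h were tested. A single library did not account for it, since the lowest median with 1 of 6 libraries left out was 0.54. More RNA without a poly-A tail of every kind stays open. Of 40 other RNAs counted as such, 33 were higher and none lower, with a median of 0.775 (SE 0.181). However, 36 of them are histone genes, so this mostly repeats the rise of the histones. Some histone transcripts may carry a tail, so these genes are not clean markers of RNA without one. Of the 4 others only RN7SK rose (0.78 ± 0.09), and RNU6-8 (0.01 ± 0.10), RNU7-1 (0.00 ± 0.11) and RN7SL1 (-0.081, SE 0.151) were not called, which goes against a rise of every kind. RN7SL1 had only 10 to 56 reads, and RNU6-8 and RNU7-1 had means of 7.37 and 9.55 normalised reads with the empty vector at 24 h, too few to exclude it. The share of mitochondrial rRNA moved with the snoRNAs and was not part of this test. The share on 22 mitochondrial tRNA genes, also outside the test, did not rise. At 24 h in DMSO it was 0.0109% ± 0.0017 with the empty vector and 0.0091% ± 0.0031 with methionase (SD, n = 3 per group). In drug-treated cells it was 0.0142% ± 0.0012 with the empty vector and 0.0081% ± 0.0005 with methionase. In empty vector cells at 24 h, the histone share was 0.0189% ± 0.0008 in DMSO and 0.0848% ± 0.0089 with Vps34-IN1. The snoRNA share was 0.0149% ± 0.0033 and 0.0251% ± 0.0057 in the same groups. These classes thus rose by unlike amounts with the drug alone, which was not a test of the methionase difference. Higher host transcripts stay open as well. The snoRNAs exceeded their hosts by a median of 0.353 (SE 0.041) over 160 of them, and its interval reached below the bound of 0.3. The medians were 0.651 for these snoRNAs and 0.263 for their hosts. The variance-stabilised scale understates changes of genes with few reads, so the difference may be too small for snoRNAs with few reads. The SE also counts snoRNAs of the same host separately. This test therefore cannot decide how far higher hosts account for the rise. A different yield of RNA without a tail and a biological change of snoRNAs cannot be told apart here.

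Ribosomal protein pseudogenes were lower at 24 h than at 12 h with the empty vector, with 64 of 163 lower and 2 higher (adjusted p = 0.03741 with an estimated correlation). Lower parent transcripts would move the ribosomal protein genes too, and their median was -0.016 (SE 0.018), which argues against that explanation. Reads shared with parent genes that moved for the whole class stay open, because the median over all tested pseudogenes of the class, -0.236 (SE 0.036), has the same sign in either case. No biological explanation was tested.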
